A study of Mus musculus with 7 samples.

How the data were processed

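Total RNA of P19 cells, 4 untreated samples and 3 samples exposed to 5 nM myxothiazol for 12 h, was labelled with Cy3 and hybridised to single-colour Agilent mouse arrays, 1 sample per array, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The spot files hold intensity values from Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The processed intensity is background subtracted and spatially detrended within an array by that software and is not normalized between arrays, per the file headers. The flags for spots well above background, saturated spots and outlier spots in these files are other values deposited by the authors. The deposited series table holds log2 values that the authors normalized between arrays. Each of its 7 columns has a median of 6.20, and columns differ by at most 0.0172 at any rank, as quantile normalization gives. Their correlation with the log2 processed signal of the same array was at least 0.994. The method behind the deposited table is not given in the sources used here beyond what its values show.

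The main values were the log2 of the processed signal minus the array's 75th percentile over spots that were not controls. Control spots and outlier spots were left out, and spots of 1 probe were averaged, which gave 56605 probes. The files name probes by accession, so gene symbols were taken from a RefSeq gene table of assembly GRCm38, matched on accessions without versions. Of the probes, 32994 (58.3%) matched 1 gene, for 22911 symbols, and the other 23611 were kept as unnamed transcripts. No coordinates are given because the array's design names another build. A probe was tested if it was well above background on every array of at least 1 group and had a value on at least 2 arrays of each group. A gene was represented by its brightest tested probe. For 74 changed genes, probes passed in both directions.

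Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on all 7 arrays, without covariates, with Benjamini-Hochberg adjustment over the 25168 genes and unnamed transcripts and a threshold of 0.05. For gene lists, camera of limma was used with a preset correlation of 0.01 between genes, adjusted over the 28 lists with at least 5 measured members of the 29 fixed. Camera was repeated with a correlation estimated from the arrays. All 15 lists called with the preset correlation missed the threshold with the estimated one. The median of all genes was -0.09 in log2 change under the main scaling, and it moved by less than 0.1 under the other scalings. The median standard error of a log2 change was 0.13.

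The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold whose treated arrays all lay beyond all control arrays, leaving out clone, locus and predicted-gene names. It added the 4 members of each list with the smallest adjusted p, and 15 genes regardless of result (Trp53, Cdkn1a, Mdm2, Atf4, Ddit3, Gdf15, Pou5f1, Nanog, Sox2, Dhodh, Cad, Umps, Cyc1, Uqcrc1 and Uqcrfs1). Genes named outside the rule are said to have been chosen after their values were seen. Markers of neuroectoderm, mesoderm and primitive streak, endoderm, fibroblasts and leukocytes were the lists for other cell types.

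The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' deposited log2 values, no filter on dim probes, a filter asking for signal on all arrays, outlier spots kept, the mean of a gene's probes, slide as a fixed or a random block, slide 1 alone, replicate number as a block, array weights, a variance trend, a threshold of 0.01, fry in place of camera, and each sample left out in turn. Normexp was run on the median spot and background intensity, since the files used here hold no mean spot intensity. Slide row as a block and row 1 alone were added after seeing that the arrays in row 2 had fewer probes above background.

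The depth of an array was judged by its share of spots well above background, from 51.0% to 65.8%, and the 75th percentile of its processed signal ran from 861 to 1999. The software's own quality summary asked for evaluation of control 3, myxothiazol 2 and myxothiazol 3 and passed the other 4 arrays. The procedure was tested on simulated data for the same comparison, with 25102 genes, of which 200 drawn at random were changed and 1 list was shifted. Of genes changed by 1 on the log2 scale, 67.0% were recovered, and of those changed by 0.5, 8.00%. No recovered gene had the wrong direction, and 1.30% of the calls were false. A far larger share of genes changed in the data (40.5%), where the adjusted threshold is therefore less strict. These recovery rates do not carry over to the real comparison. A simulated shift of 1 list by -0.4 was called, and 0 of the other 27 lists were. Genes were simulated as independent, so this could not show false list calls that come from correlation between genes. In the data the estimated correlation reached 0.77, for ribosomal proteins.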

Results

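RNA from P19 cells was profiled on 7 single-colour mouse microarrays. P19 is a mouse embryonal carcinoma line that keeps features of early embryonic stem cells and can be driven into several lineages in culture. Of the 7 arrays, 4 carried RNA of untreated cells and 3 carried RNA of cells exposed to 5 nM myxothiazol for 12 h. Myxothiazol blocks complex III of the mitochondrial respiratory chain, where electrons pass from ubiquinol to cytochrome c. The comparison asks which transcripts differ between treated and untreated cells at that time. Each array held 59305 spots that were not controls. The share of these spots well above background was 65.6%, 64.2%, 51.0% and 64.7% for controls 1 to 4, and 64.7%, 60.9% and 65.8% for myxothiazol samples 1 to 3. No spot was saturated, and the number of arrays limits the precision. The series describes the samples as independent without saying how they were separated, so the p-values measure the spread between these samples.

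Myxothiazol was followed by a broad change in gene expression. Of 25168 genes and unnamed transcripts tested, 10203 (40.5%) differed between the groups, with 4792 higher and 5411 lower in treated cells. Which side was larger depended on the setting, with 5416 higher and 4407 lower under quantile normalization, 4621 and 3949 with median scaling, 5401 and 4378 with the authors' values, and 3619 and 3188 without myxothiazol replicate 2. Sp5, a transcription factor gene known as a target of Wnt signalling, had the largest rise among the named genes, 55.3-fold (log2 change 5.79, SE 0.12, n = 4 and 3, limma adjusted p = 1.2e-06). Its normalized log2 signal was -2.07 ± 0.13 (SD, n = 4) in control and 3.72 ± 0.17 (SD, n = 3) in treated cells. Other large rises were seen in homeobox and other developmental transcription factor genes. Cdx2, which helps specify the posterior embryo and the trophectoderm, rose 18.9-fold, and its paralogue Cdx1 rose 14.9-fold. Evx1, a gene of the primitive streak, rose 12.0-fold. Hoxa1 rose 10.4-fold, Six2 10.1-fold and Foxb1 14.3-fold. Hoxb1 was not well above background in any control and was at least 8.98-fold higher in treated cells. The noncoding Evx1os was likewise below background in the controls and was at least 4.24-fold higher. Such bounds set the mean of the brighter group against the lowest signal called well above background on each array of the dimmer group. Svop rose by 3.71 on the log2 scale, Ascl4 by 3.58 and Arhgap24 by 3.55. Foxb1, Svop and Arhgap24 were well above background on 3 of the 4 control arrays and Ascl4 on 1. Of the genes named from the lists, Rrm2b, Gdf15 and Irf7 were so on 3 control arrays and Cd52 and Usp18 on 2.

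The largest fall among the named genes was that of Snhg5, a host gene of small nucleolar RNAs, with a log2 change of -3.99 (SE 0.16, limma adjusted p = 1.8e-05). Cntf, which encodes a neurotrophic cytokine, changed by -3.56 on the log2 scale. Mthfd2l, a mitochondrial enzyme of one-carbon metabolism, changed by -3.20, and Stc1, which encodes a secreted glycoprotein, by -3.01. The noncoding transcripts Rab26os, Mirg and Platr14 changed by -3.27, -2.58 and -2.43. Lpar2, a lysophosphatidic acid receptor, changed by -2.73, Aoc3 by -2.57, Nt5dc1 by -2.46 and the linker histone gene H1f3 by -2.43. Ctsk, a lysosomal protease, was not well above background in any treated sample and was at least 3.35-fold lower there. Stc1 was well above background on 1 of the 3 treated arrays and Aoc3 on 2. Among genes with a symbol, 1095 were at least 2-fold higher and 365 at least 2-fold lower. Including unnamed transcripts, 2203 genes changed at least 2-fold, 1478 up and 725 down. With normexp background correction, which compresses dim signals, 1013 did, and 1422 did among probes well above background on every array. A gene dim in 1 group was tested only if all arrays of the other group had signal. This asks less of the 3 treated arrays than of the 4 controls, which include control 3 with 51.0% of spots above background. The filter may thus add to the excess of rises here and in the gene lists. Among probes well above background on every array, 3907 genes were higher and 5579 lower at any size of change. The 2-fold changes were not split by direction there.

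**Figure D1:**
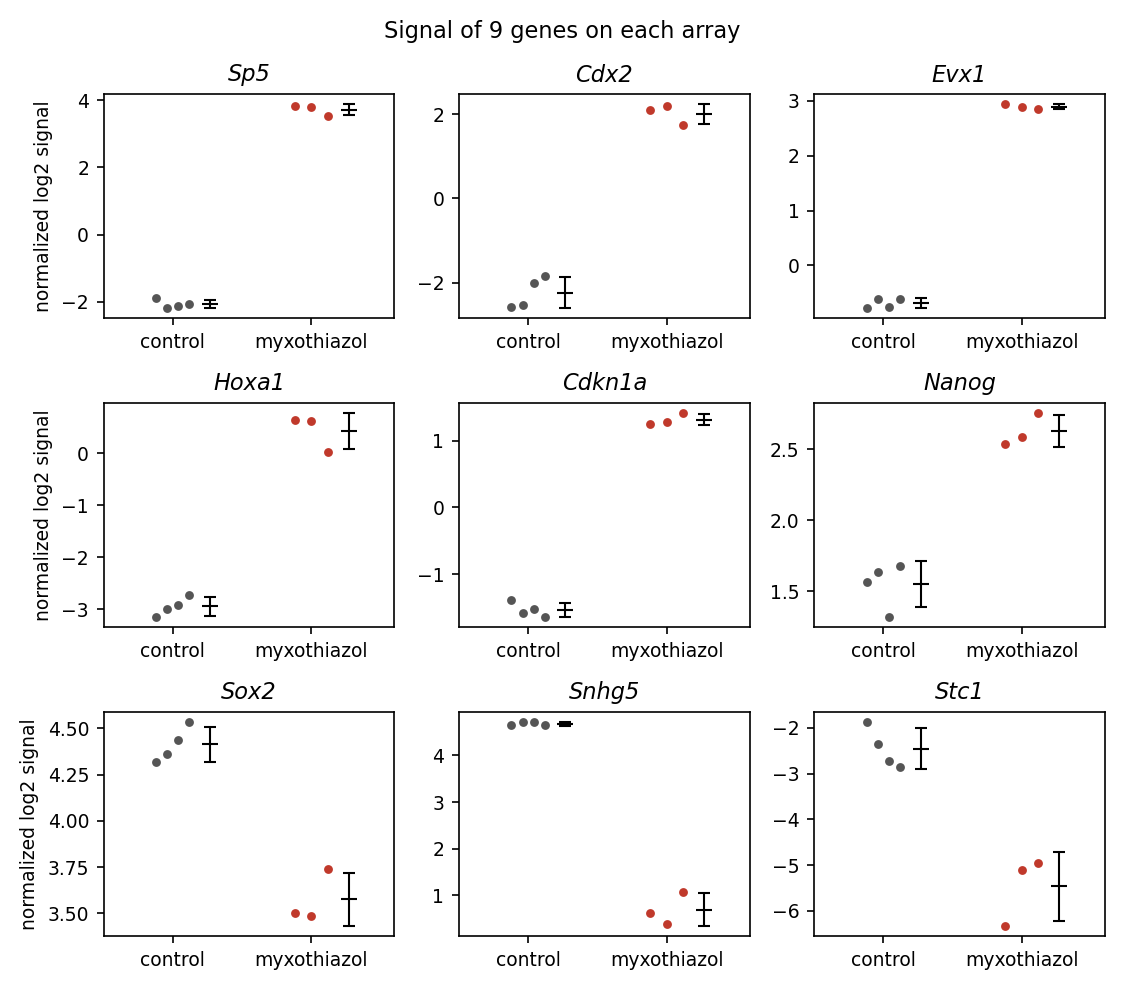
Normalized log2 signal (vertical axis) of 9 genes on each of the 4 control (grey) and 3 myxothiazol (red) arrays, with the group mean and 1 SD as bars beside the points. The treated arrays lie beyond all control arrays for each of these genes, with log2 changes from 5.79 for Sp5 to -3.99 for Snhg5.

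The arrays lay on 2 slides, and both slides held both groups. With slide as a block 10699 genes differed between the groups. Of the 10197 changed genes with values on slide 2, which held 1 control and 1 treated array, 10167 (99.7%) had the same direction there, and all 10203 did within slide 1. The 2 arrays in the second row of slide 1, control 3 and myxothiazol 2, had the fewest probes above background. Without them 5809 genes differed, 3080 higher and 2729 lower. Between-group correlations across genes ran from 0.971 to 0.981, below all within-group correlations, which ran from 0.99 to 0.996. Genes are not independent replicates in such correlations. The groups did not overlap for 47.1% of the genes, where chance gives 5.71%.

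Mesoderm and primitive streak markers rose together. Of 18 measured members, 15 rose and none fell (16 and 0 adjusted over the list alone), and their median log2 change was 1.44. Beside Cdx2, Cdx1 and Evx1, Wnt3, a ligand needed to form the primitive streak, rose 4.94-fold (log2 change 2.30, SE 0.10). The list's shift passed the camera test (adjusted p = 1.7e-10), and its adjusted p was 0.114 with an estimated correlation. Its median was 1.41 within slide 1, 1.11 within slide 2 and 1.45 with slide as a block. The median was 0.91 with normexp correction.

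Genes that respond to retinoic acid, which drives P19 cells towards neural fates, also rose, 9 of 11 measured and none falling (9 and 1 adjusted over the list alone). Their median log2 change was 1.14, with camera adjusted p = 2.6e-06 and adjusted p = 0.167 with an estimated correlation. Hoxb1 and Hoxa1 led this list. Meis2, a homeobox partner of Hox proteins, rose 3.23-fold, and Rbp1, a retinol carrier, rose 2.17-fold. The list median was 1.19 within slide 1, 1.16 within slide 2 and 1.15 with slide as a block.

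Markers of other cell types were also higher in part. Among 18 endoderm markers, 12 rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.73. Foxa1, an endodermal transcription factor, rose by 1.5 on the log2 scale, Pth1r by 1.25 and the simple-epithelium keratins Krt8 and Krt18 by 1.07 and 0.96. The list's shift passed camera with adjusted p = 0.0021, and had adjusted p = 0.242 with an estimated correlation. Its medians were 0.91 and 0.40 within slides 1 and 2 and 0.74 with slide as a block. It was 0.39 with normexp correction. Among 12 fibroblast and stromal markers, 7 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.58. Tagln and Vim, cytoskeletal genes, rose by 1.43 and 1.17, Thy1 by 1.16 and the collagen gene Col1a2 by 1.15. The camera adjusted p was 0.0060, and adjusted p = 0.188 with an estimated correlation. The medians were 0.57 and 0.59 within slides 1 and 2 and 0.58 with slide as a block.

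Neuroectoderm markers were mixed, with 11 of 25 higher and 3 lower (12 and 4 adjusted over the list alone). Gbx2, a hindbrain patterning gene, rose by 2.97 on the log2 scale, the radial glia gene Fabp7 by 1.63, the Notch ligand Dll1 by 1.34 and the neurofilament gene Nefl by 0.88. The list median was 0.26, with camera adjusted p = 0.025 and adjusted p = 0.242 with an estimated correlation. The medians were 0.23 within both slides and 0.28 with slide as a block. With quantile normalization the camera call was lost (adjusted p = 0.054), and with normexp correction the median was 0.11. Of 6 leukocyte markers, 2 rose, Cd68 by 1.29 and Cd52 by 1.22, and none fell (2 and 0 adjusted over the list alone). Cd14 at 0.31 (-0.21 at its other probe) and Fcer1g at -0.29 did not pass, nor did the list (camera adjusted p = 0.367), though fry passed it as higher (adjusted p = 0.019).

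Pluripotency genes moved in both directions, with 8 of 36 higher and 14 lower (8 and 14 adjusted over the list alone). Tbx3 and the naive-state regulators Nr5a2 and Tfcp2l1 were among the genes that rose. Tbx3 rose 7.24-fold, Nr5a2 4.74-fold and Tfcp2l1 4.45-fold, while Foxd3 changed by -2.18 on the log2 scale. Nanog rose 2.11-fold (log2 change 1.08, SE 0.12, limma adjusted p = 0.00039), and its other probe, at 1.28, did not pass. Sox2 changed by -0.84 (SE 0.10, limma adjusted p = 0.00071). Pou5f1, which encodes Oct4, had a log2 change of -0.18 (SE 0.15, limma adjusted p = 0.391) and did not pass. The list as a whole did not pass camera (adjusted p = 0.405).

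**Figure D2:**
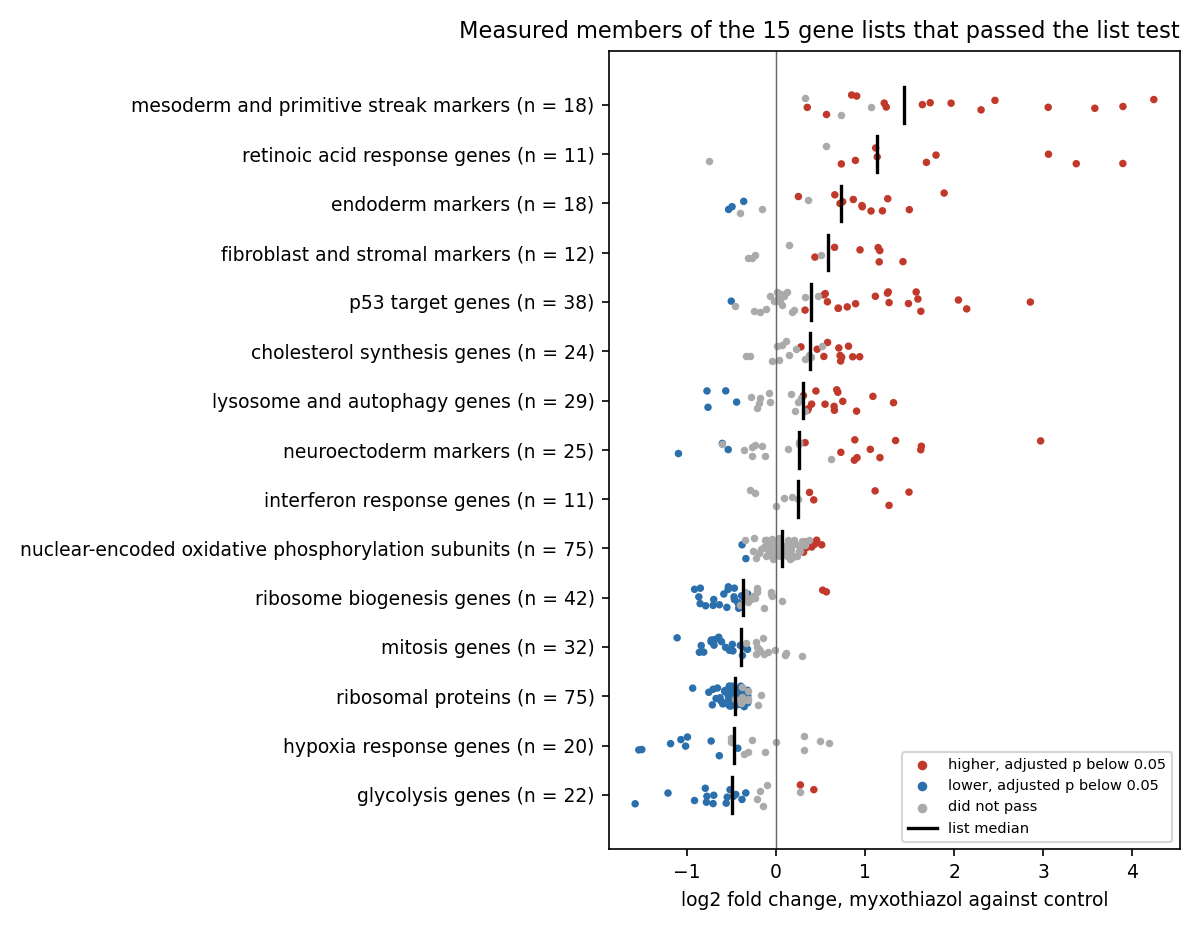
Log2 fold change of myxothiazol against control cells (horizontal axis) for each measured member of the 15 gene lists that passed the camera test, with the list median as a vertical bar. The medians run from 1.44 for mesoderm and primitive streak markers to -0.50 for glycolysis genes, and the ribosomal protein median of -0.46 becomes -0.0084 with quantile normalization.

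Targets of p53, the stress-activated tumour suppressor, rose in 19 of 38 cases, and 1 fell (20 and 1 adjusted over the list alone). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 7.24-fold (log2 change 2.86, SE 0.10, limma adjusted p = 1.4e-05). Its other, dimmer probe had a log2 change of 0.86 and did not pass (limma adjusted p = 0.063). Plk2, a stress-induced kinase, rose 3.02-fold, Rrm2b, a ribonucleotide reductase subunit used in DNA repair, 2.80-fold and the adenylate kinase Ak1 2.17-fold. The list median was 0.40, with camera adjusted p = 7.6e-06 and adjusted p = 0.242 with an estimated correlation. The medians were 0.41 and 0.34 within slides 1 and 2 and 0.42 with slide as a block. Mdm2, a p53 target and its main negative regulator, had a log2 change of 0.09 (SE 0.10) at its brightest probe and did not pass there, while its other, dimmer probe rose by 0.61 (limma adjusted p = 0.0095). Gdf15 had -0.46 (SE 0.19) and Trp53 itself -0.26 (SE 0.10), and neither passed.

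Mitosis genes fell. Of 32 measured, 19 fell and none rose (19 and 0 adjusted over the list alone), with a median log2 change of -0.39. Plk1, a kinase of mitotic entry, changed by -1.11 on the log2 scale, the topoisomerase gene Top2a by -0.84 and the kinetochore genes Cenpf and Cenpe by -0.73 and -0.64. This fall passed camera with adjusted p = 2.9e-05, and had adjusted p = 0.288 with an estimated correlation. The median was -0.43 within slide 1, -0.45 within slide 2 and -0.39 with slide as a block. DNA replication and S phase genes showed no shared direction, with 9 of 35 higher and 4 lower (9 and 4 adjusted over the list alone). E2f1 rose by 0.97, Pold1 by 0.70 and Rfc4 by 0.66, and Ccne1 changed by -0.78. Their median of -0.04 and mean of 0.03 differed in sign, and camera gave adjusted p = 0.534. With quantile normalization the median was 0.16 and the list passed camera as higher (adjusted p = 0.030).

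Glycolysis genes fell, with 15 of 22 lower and 2 higher (15 and 3 adjusted over the list alone). Slc16a3, the lactate exporter MCT4, changed by -1.58 on the log2 scale, hexokinase 2 (Hk2) by -1.21, Tpi1 by -0.92 and Pgam1 by -0.79. The median was -0.50, with camera adjusted p = 7.1e-04 and adjusted p = 0.167 with an estimated correlation. It was -0.46 and -0.52 within slides 1 and 2 and -0.50 with slide as a block. With quantile normalization the median was -0.16, with 9 members lower and 3 higher. Hypoxia response genes, several of which also act in metabolism, fell in 9 of 20 cases and none rose (11 and 1 adjusted over the list alone). Bnip3, a mitophagy receptor, changed by -1.54, Ankrd37 by -1.51, the mitochondrial adenylate kinase Ak4 by -1.18 and the histone demethylase Kdm3a by -0.99. Their median was -0.47, with camera adjusted p = 0.0048 and adjusted p = 0.558 with an estimated correlation. The medians were -0.52 and -0.32 within slides 1 and 2 and -0.46 with slide as a block.

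Cholesterol synthesis genes rose in 11 of 24 cases and none fell (12 and 1 adjusted over the list alone). Cyp51, a sterol demethylase, rose by 0.94 on the log2 scale, Dhcr7 by 0.74, Mvd by 0.73 and Pcsk9, a regulator of the LDL receptor, by 0.71. The median was 0.38, with camera adjusted p = 9.2e-04 and adjusted p = 0.558 with an estimated correlation. It was 0.47 within slide 1, 0.22 within slide 2 and 0.39 with slide as a block. Lysosome and autophagy genes rose in 14 of 29 cases and 4 fell (14 and 4 adjusted over the list alone). The hexosaminidase subunits Hexb and Hexa rose by 1.09 and 0.90 and the protease Ctsb by 0.68, while Fnip2 changed by -0.76. The median was 0.31, with camera adjusted p = 0.014 and adjusted p = 0.586 with an estimated correlation. It was 0.36 and 0.14 within slides 1 and 2 and 0.32 with slide as a block. Interferon response genes rose in 5 of 11 cases and none fell (5 and 0 adjusted over the list alone), with a median of 0.24. Irf7 rose by 1.49, Oasl2 by 1.27, Usp18 by 1.11 and Stat1 by 0.42 (0.26 at its other probe, which did not pass). Camera gave adjusted p = 0.029 and, with an estimated correlation, adjusted p = 0.242. The medians were 0.23 and 0.38 within slides 1 and 2 and 0.26 with slide as a block. With normexp correction Usp18 and Stat1 did not pass, and the list's call was lost without myxothiazol replicate 3 (adjusted p = 0.053) and without a filter on dim probes (adjusted p = 0.079).

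Transcripts of the respiratory chain, the pathway that myxothiazol acts on, had small changes. Of 75 nuclear-encoded oxidative phosphorylation subunits, 11 rose and 2 fell (4 and 0 adjusted over the list alone). The complex I subunits Ndufb9, Ndufb2, Ndufa11 and Ndufc1 rose by 0.51, 0.46, 0.43 and 0.35 on the log2 scale. The median was 0.06, with camera adjusted p = 0.034 and adjusted p = 0.745 with an estimated correlation. It was 0.11 within slide 1, -0.02 within slide 2 and 0.08 with slide as a block. With quantile normalization 49 members rose, none fell and the median was 0.33. The call was lost without control replicate 1, without control replicate 2 and without myxothiazol replicate 1, with adjusted p up to 0.379. Of 14 complex III subunits and assembly factors, 3 rose and 1 fell (2 and 0 adjusted over the list alone). The assembly factors Ttc19 and Uqcc2 rose by 0.80 and 0.61. Uqcc1 had 0.34 at its brightest probe and -0.57 at another. Uqcrh changed by -0.34, a change that became 0.010 with quantile normalization. Uqcrc1, Cyc1 and Uqcrfs1 had log2 changes of 0.05, 0.05 and -0.26 and did not pass, though Uqcrc1 passed with quantile normalization (0.27). Camera gave adjusted p = 0.348 for this list, and adjusted p = 0.011 as higher with quantile normalization.

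Among 13 mitochondrial biogenesis and mtDNA expression genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone). Ppargc1a, a coactivator of mitochondrial gene expression, was below background in all controls and at least 2.06-fold higher in treated cells. It did not pass with normexp correction. Ppargc1b and Polg rose by 0.66 and 0.63 on the log2 scale, and Gabpa changed by -0.59. The other probe of Ppargc1b had the opposite sign, -0.30, and did not pass (limma adjusted p = 0.158). The list did not pass (camera adjusted p = 0.702), and its median of -0.06 and mean of 0.09 differed in sign. With normexp correction the median was 0.01. No probe was matched to a mitochondrially encoded protein gene, so that list was not analysed here. Pyrimidine nucleotide synthesis depends on the respiratory chain through dihydroorotate dehydrogenase, encoded by Dhodh. Of 23 genes of pyrimidine metabolism, 4 rose and 3 fell (4 and 3 adjusted over the list alone), and camera gave adjusted p = 0.291. Cad, which starts the pathway, rose by 0.52 at its brightest probe and had 0.13 at the other, which did not pass (limma adjusted p = 0.688). Dctd rose by 0.83 and Tk2 by 0.72, and Dut changed by -0.52. Dhodh and Umps had log2 changes of 0.05 (SE 0.11) and -0.04 (SE 0.11) and did not pass. With quantile normalization the list passed camera as higher (adjusted p = 0.030).

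The ATF4, aminoacyl-tRNA synthetase, endoplasmic reticulum and heat shock lists did not pass camera in the main setting, though fry passed the last of these and the endoplasmic reticulum list (both adjusted p = 0.0038) and the synthetases (adjusted p = 0.011) as lower. Other genes of the same brightness were also lower. Of brightness-matched lists, 39.7%, 21.1% and 39.2% were as low as the heat shock, endoplasmic reticulum and synthetase lists. The ATF4 list went the other way, since 99.7% of its matched lists were as low as it or lower. Its median was 0.13 against a matched median of -0.14. Of 35 targets of ATF4 and the integrated stress response, which mitochondrial dysfunction is known to activate, 8 rose and 5 fell (8 and 5 adjusted over the list alone). Ddit3, which encodes the transcription factor CHOP, rose 2.82-fold (log2 change 1.5, SE 0.23, limma adjusted p = 0.0018). Nupr1 and Atf5 rose by 1.19 and 0.92, and Slc38a2 and Stc2 changed by -0.92 and -0.70. Atf4 changed by -0.54 (SE 0.18, limma adjusted p = 0.041), with -0.39 at its other probe, which did not pass, and did not pass with quantile normalization. Camera gave adjusted p = 0.227, and the list passed as higher with normexp correction (adjusted p = 0.035) and without myxothiazol replicate 3 (adjusted p = 0.042). Of 20 cytosolic aminoacyl-tRNA synthetases, 1 rose and 5 fell (1 and 5 adjusted over the list alone). Farsb, Tars and Qars changed by -0.75, -0.56 and -0.42, and Nars rose by 0.38 (list adjusted p = 0.104 by camera). The other probe of Qars, at -0.49, did not pass. Of 20 endoplasmic reticulum chaperones and unfolded protein response genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone). Xbp1, a transcription factor of that response, changed by -1.56, Hsp90b1 by -0.92 and Hspa5 by -0.57, while Derl3 rose by 0.74 (list adjusted p = 0.104 by camera).

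Of 17 heat shock genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone). Hspa8, Hspa4 and Hsph1 changed by -0.88, -0.84 and -0.82, and Hspb8 rose by 0.72 (list adjusted p = 0.119 by camera). With quantile normalization 5 heat shock genes rose and 3 fell, and the list median was -0.20 against -0.27. Of 13 mitochondrial chaperones and proteases, 2 rose and 4 fell (2 and 4 adjusted over the list alone). Yme1l1 and Hspa9 changed by -0.60 and -0.45, and Spg7 and Clpx rose by 0.53 and 0.49 (list adjusted p = 0.509 by camera). The median of -0.17 changed sign with quantile normalization, to 0.08, with 3 higher and 3 lower. Of 22 NRF2 antioxidant genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone). Ephx1, Nqo1 and Gstm1 rose by 1.75, 1.01 and 0.68, and Cbr3 changed by -0.66 (list adjusted p = 0.448 by camera). The NRF2 median was -0.05 and its mean 0.11, and the median was 0.23 with quantile normalization. Of 20 immediate early genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone). Btg2, also a p53 target, rose by 1.57 and Jun by 0.61, and Ier3 and Egr2 changed by -1.98 and -1.5. The list did not pass camera (adjusted p = 0.648, direction up), while the list's median was -0.09 and its mean -0.05.

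Ribosome biogenesis genes fell in 24 of 42 cases and 2 rose (26 and 2 adjusted over the list alone). The nucleolar genes Gnl3 and Npm1 changed by -0.87 and -0.85 on the log2 scale, the RNA polymerase I subunit gene Polr1c by -0.85 and Wdr43 by -0.79. The median was -0.38, with camera adjusted p = 2.0e-05 and adjusted p = 0.558 with an estimated correlation. It was -0.36 and -0.42 within slides 1 and 2 and -0.38 with slide as a block, and -0.23 with quantile normalization. Of 75 ribosomal protein genes, 64 were lower and none higher (73 and 0 adjusted over the list alone), with a median of -0.46 under scaling to the 75th percentile. Rpl7, Rpl7a, Rpl29 and Rpl13a changed by -0.76, -0.71, -0.63 and -0.58. Camera gave adjusted p = 1.9e-11, and adjusted p = 0.558 with an estimated correlation. The median was -0.39 and -0.62 within slides 1 and 2 and -0.47 with slide as a block. With quantile normalization the call was lost (adjusted p = 0.812), the median was -0.0084, and 5 members were lower and 1 higher. Ribosomal protein probes lie among the brightest on the array. When all tested genes were split by mean signal into 10 groups, the brightest group had a median change of -0.30 under scaling to the 75th percentile and -0.0064 with quantile normalization. Quantile normalization gives every array the same values at each rank. It therefore draws the brightest genes towards 0 whether or not their fall is real, and the loss of the call cannot tell these cases apart.

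**Figure D3:**
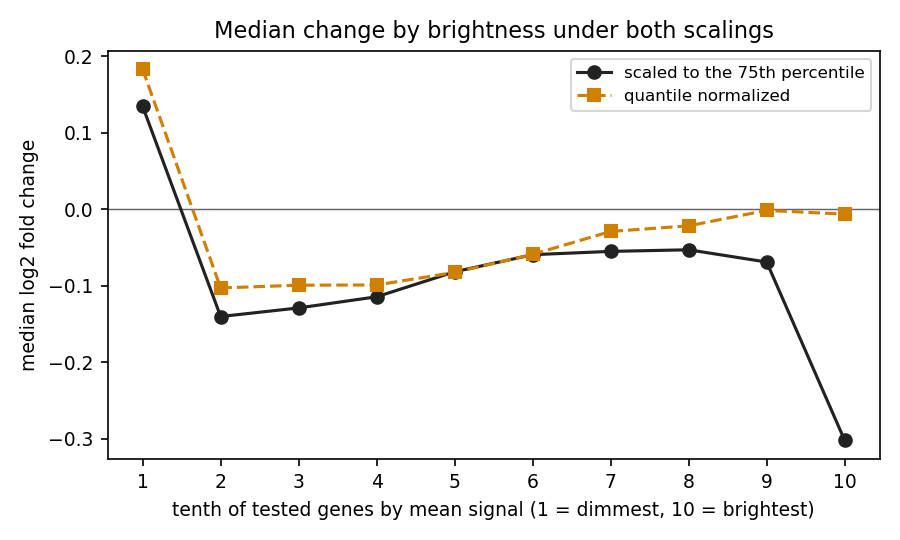
Median log2 fold change of myxothiazol against control (vertical axis) for the tested genes split by mean signal into 10 groups of 2516 or 2517 genes (horizontal axis), under scaling to the 75th percentile (black circles) and quantile normalization (orange squares). Both curves lie close together except among the brightest genes, where the medians are -0.30 and -0.0064. Quantile normalization sets the arrays equal at each rank, which by itself holds the brightest group near 0.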

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

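The tests of other splits of the arrays were fixed before the data were examined. Control values were searched for single arrays far from the other 3, over 144 named genes and 3 array measures, and chance marks about 1 in 20 such groups. Of these 147, 4 stood out. Control 3 had 51.0% of its spots well above background, against 64.2% to 65.6% for the other controls. Control 1 had the lowest normalized log2 signal for the assembly factor gene Uqcc2, 4.91 against 5.09 to 5.10, and for the replication factor gene Rfc4, 5.02 against 5.10 to 5.12. Control 4 had the highest signal for the polymerase gene Pold1, 4.73 against 4.69 in each of the others.

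The 7 arrays can be split into 4 and 3 in 35 ways. Only 1 of the 35 splits, the real one, gave 10203 or more changed genes, and the highest count among the others was 1. The same held for the 4792 genes higher in treated cells (highest other 0) and the 5411 lower (highest other 1). It also held for the 2203 changed at least 2-fold (highest other 1). However, every other split mixes treated and control arrays on at least 1 side. The group difference then adds to the spread within that side and keeps counts near 0. The real split thus stands out, but the size of this gap does not exclude a chance division. The real split was also the only 1 to give as many as 15 lists called by camera with its preset correlation. However, 3 other splits gave 14 lists each, 1 of them the 3 controls of slide 1 against the rest. These 3 keep all or most of the treated arrays on one side, so they still carry part of the difference between the groups. The 18 most balanced splits, with 1 treated array among 3, gave 0 to 9 lists (median 3), and the treatment is not fully balanced in these either. In the real split no list was called with an estimated correlation.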

How the results depend on the processing

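The alternatives slide row as a block and row 1 arrays alone were chosen after seeing the data. Over the 23 alternatives run on single genes, where 15 pairs of a named gene and an alternative had no test, 132 of the 133 named genes that passed kept their direction, and 117 of all 144 named genes also kept their side of the threshold. The exception in direction was Uqcrh, at 0.010 with quantile normalization and 0.0092 with the authors' deposited values, which are also quantile normalized. The cause was not tested for any change below unless one is given. The number of changed genes was 6047 at a threshold of 0.01, 6761 without a filter on dim probes, where more genes were tested, and 5809 in row 1 alone, with fewer arrays. Genes lower in treated cells numbered 3489 without the filter, 8629 with array weights and 2729 in row 1 alone, where 3080 were higher. Genes changed at least 2-fold numbered 1013 with normexp correction and 1422 among probes above background on all arrays. Higher calls were 47.0% of all calls in the main setting and 41.9% to 55.2% under the other scalings. Signal over background limits what can be said of dim genes.

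The replicate numbers 1 to 3 occur in both groups but did not pair the arrays. Deviations from the group means correlated at 0.035, 0.087 and -0.094 for same-numbered arrays, and not every array correlated best with its own number. With replicate number as a block, on 6 arrays, 6754 genes changed, 3127 of them lower, and no list changed its call.

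With an estimated correlation, camera lost every list it had called. The adjusted p was 0.114 for mesoderm and primitive streak markers, 0.167 for retinoic acid response and glycolysis genes, 0.188 for fibroblast markers, and 0.242 for p53 targets and for neuroectoderm, endoderm and interferon response genes. It was 0.288 for mitosis genes, 0.558 for hypoxia response, cholesterol synthesis, ribosome biogenesis and ribosomal protein genes, 0.586 for lysosome and autophagy genes and 0.745 for oxidative phosphorylation subunits. Fry, which asks only whether a list moves one way, passed the aminoacyl-tRNA synthetases (0.011), leukocyte markers (0.019), the endoplasmic reticulum list and the heat shock list (both 0.0038), and not oxidative phosphorylation subunits (0.279). With quantile normalization and the authors' values, adjusted p was 0.812 and 0.809 for ribosomal proteins and 0.054 and 0.052 for neuroectoderm markers, which no longer passed. It was 0.011 and 0.011 for complex III genes, 0.030 and 0.030 for DNA replication and S phase genes, and 0.030 and 0.030 for pyrimidine metabolism genes, which passed as higher. Normexp correction passed the ATF4 list (0.035). Neuroectoderm markers missed the threshold among probes above background on all arrays (0.088) and in row 1 alone (0.073). Interferon response genes missed it without the filter (0.079), among probes above background on all arrays (0.097) and with array weights (0.056). Array weights also ended the oxidative phosphorylation call (0.165). Camera takes no random block, so lists were not run with slide as one. Gene counts with that block and every list with slide as a fixed block kept their side.

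With each sample left out in turn, 6807 to 10181 genes changed, with 3619 to 4661 higher, 3188 to 5520 lower and 2158 to 2584 changed at least 2-fold. The lowest count of lower genes, 3188, came without myxothiazol replicate 2. The adjusted p ran from 0.0080 to 0.379 for oxidative phosphorylation subunits, from 0.042 to 0.440 for the ATF4 list and from 0.019 to 0.053 for interferon response genes. The first call was lost without control replicate 1, control replicate 2 or myxothiazol replicate 1. The ATF4 list passed, and the interferon list missed, only without myxothiazol replicate 3. All other lists kept their side of the threshold.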

Other observations

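The Wnt, Hox, host gene and histone groups in this part were chosen by symbol after the data were seen. The tests in it were chosen after the results they measure were seen, except camera for mesoderm and primitive streak markers, which was planned. Of 16 measured Wnt ligand genes, 10 rose and 1, Wnt7b, fell (log2 change -0.37). Wnt6 rose by 2.89 on the log2 scale and Wnt9b by 1.93. The median was 1.43, or 0.95 with the 3 members below background in all controls set at their bound, and 0.49 with normexp correction. Wnt2, Wnt4, Wnt6, Wnt9b and Wnt10b were also not well above background on every control array. These and the 3 members at a bound entered the test only through the treated arrays, which favours rises. The counts, median and camera result of this group hold that bias, and its size was not measured. Camera gave adjusted p = 3.0e-06 over the 4 groups chosen this way, and adjusted p = 0.015 with an estimated correlation. Known targets of Wnt signalling did not all move together. Beside Sp5, Axin2 and Nkd1 rose by 1.53 and 2.20, and Dkk1 and Dkk4, which encode secreted Wnt inhibitors, by 2.27 and 3.01. Lgr5 rose by 0.93. Dkk1 and Lgr5 were well above background on 1 of the 4 control arrays, and Dkk4, Wnt6, Wnt9b and Rnf43 were on 3. Ccnd1 changed by -0.85 and Lef1 by -0.43. Notum, Rnf43, Tcf7 and Znrf3 had changes of -0.0067, 0.0038, 0.0021 and 0.022 and did not pass. The other probe of Notum fell by 0.49 (log2 change -0.49, limma adjusted p = 0.041). Of 21 measured Hox genes, 14 rose and 1, Hoxa7, fell (-1.11), with a median of 1.01, or 0.85 with 3 members at their bound and 0.38 with normexp correction. Hoxa10, counted among the risers, was below background in all controls at its tested probe but not at every probe, so it was given no bound, and the median was 0.84 with its change set to 0. The Hox group's camera adjusted p was 4.7e-07, and adjusted p = 0.10 with an estimated correlation. Hoxb3, counted as unchanged at its brightest probe (-0.0017), rose by 2.80 at its other probe (limma adjusted p = 0.00044). Hox members not well above background on every control array, such as Hoxa3 with 2, also entered only through the treated arrays. This favours rises in the Hox group as in the Wnt group.

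Beside Snhg5, other host genes of small nucleolar RNAs fell. Of 14 measured, 11 fell and 1, Snhg10, rose (0.28), with a median of -0.71 (camera adjusted p = 1.7e-04, and adjusted p = 0.10 with an estimated correlation). Snhg4 changed by -2.22 and Snhg3 by -1.96, and the median stayed between -0.62 and -0.71 under the other scalings. Eif4a2, a coding gene that also hosts small nucleolar RNAs, changed by -2.39 at 1 probe and -2.06 at the other. In the imprinted cluster that holds Mirg, Rian changed by -1.27, the coding gene Dlk1 rose by 0.84, and the 4 probes of Meg3 ran from -0.07 to -1.38.

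The rise of mesoderm and primitive streak markers was weighed against 2 explanations, slide or row and a lower share of stem cells. If slide or row had made it, the list's median should be near 0 within some slide or row, but the lowest of these 4 medians was 1.11 against 1.44 over all arrays. A lower share of stem cells would raise markers of all other cell types alike only if those types grew equally and stem cells lacked the markers. Among members above background on all arrays, the 12 of this list rose by 1.58 more on average than the 51 of the neuroectoderm, endoderm, fibroblast and leukocyte lists, with means of 2.0 and 0.42. The spread of this difference over arrays was small (SE 0.054, 95% interval 1.44 to 1.72). This list was chosen because it rose most, so the permutation test of 100000 resamples took the highest contrast of any of the 5 lists (p = 9.0e-05). It treats genes as independent, and camera's call for this list was lost with an estimated correlation (adjusted p = 0.114). A rise of all markers by the same amount is argued against by the difference and its spread over arrays. A lower share as such is not decided, since the log2 rises it gives depend on the signal that stem cells already have. A treatment-linked change in the state of the cells is a hypothesis that these tests leave open, and a change in the share of streak-like cells may give the same values.

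The fall of ribosomal protein transcripts may be a loss of signal at bright probes. Lists of 75 other genes of the same brightness had a median of -0.46, and the ribosomal protein median differed from it by -0.0024, with 45.2% of 10000 matched lists as low or lower. Slide or row as the whole cause is argued against by the weakest within-slide or within-row median, -0.36 against -0.46. The median of other bright transcripts thus fell as that of ribosomal proteins did, though not every bright group fell. The matched genes included unnamed transcripts, and any that share sequence with ribosomal protein genes were not removed. Whether the arrays or the cells' abundant transcripts changed stays open. A second draw, run for every list, left histone genes among the matched genes, and there 56.4% of lists were as low as ribosomal proteins, with a matched median of -0.46. In that draw 0.15% of matched lists were as low as glycolysis genes and 0.07% as low as mitosis genes. The share was 0.01% for hypoxia response genes and 0.33% for ribosome biogenesis genes. Their matched medians were -0.32, -0.12, -0.09 and -0.20, so other genes as bright shared part of these falls. Oxidative phosphorylation subunits were higher than all of their matched lists, with a median of 0.06 against a matched median of -0.27. Of lists that did not pass camera, ATF4 targets were at or above 99.7% of theirs. The share was 99.4% for pyrimidine metabolism genes and 98.8% for complex III genes. None that missed camera stood as far below its matched lists.

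Histone genes of the replication-dependent clusters fell together. Of 43 measured, 37 fell and 1, H2bc23, rose (0.70), with a median of -1.17 and -0.97 with quantile normalization (camera adjusted p = 3.3e-15, and adjusted p = 0.10 with an estimated correlation). Paralogues share sequence, so probes of these genes may not be independent. Loss of signal at bright probes is argued against, since the median lay 0.93 below that of brightness-matched lists (difference -0.93) and 0 of 10000 such lists were as low. A lowering of all S phase transcripts alike is argued against as the main cause. The DNA replication and S phase list had a median of -0.041, and with a standard deviation of 0.391 between its members this lies above 50% of the histone median by more than that spread. That spread is between genes and is not an error of the median. Fewer cells in S phase as such is not decided, since replication gene transcripts need not follow the number of such cells. A smaller contribution of such a lowering, or a block that leaves replication gene transcripts high, is not addressed by this value.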
